A study of Drosophila melanogaster with 4 samples.

How the data were processed

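The series profiled the genomic binding of a GFP-tagged form of Lola, a BTB zinc finger transcription factor of Drosophila melanogaster, in whole embryos collected 0 to 12 h after egg laying. Per the labels, the flies carried a genomic lola transgene (isoform RJ, protein PJ) at the VK00033 landing site. Chromatin was cross-linked for 15 min in 1.8% formaldehyde and immunoprecipitated with a rabbit polyclonal antibody against GFP (ab290). Libraries were made from 2 immunoprecipitates and 2 input DNA samples. The labels do not say whether the replicates came from separate embryo collections.

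The deposited material is 1 list of peaks for the whole series, so no value belongs to a single library. Per the file headers, positions are in release 5 of the FlyBase genome and the peaks come from MACS. The submitters' processing notes name CASAVA (1.7.0.2 and 1.7.0.3), BWA, MACS2 and the build BDGP5, without stating what each was used for. How the replicates were combined, the calling threshold and the treatment of reads that map to several places are not given in the sources used here. Read numbers per library are likewise not given, so the depth of each sample is unknown.

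Each peak carries a start, an end and a score. The unit of the score is not named by the header or the labels and was worked out from the values. A ladder of values was computed as −log10 of the Poisson probability of more than k overlapping fragments, for whole k and 1 fixed background mean. The mean was chosen between 20 and 120 to match the most scores within 0.01. The deposited scores are therefore treated as −log10 p-values that the authors' caller assigned to each peak. Scores are used to describe, rank or filter peaks within this list. A peak on the ladder is called here a peak at the fixed background, and its k divided by the background mean gives a fold over background. MACS by default tests each peak against the larger of the genome-wide background and the local input, so a score off the ladder is read as a peak tested against a local input above that background. That reading rests on the default, since the settings are not given in the sources used here.

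The gene table used here belongs to release 6, and no release 5 genome or annotation was used. Coordinates were not converted. The planned placement of peaks on promoters, exons and introns, the 24 gene lists, the 21 sequence motifs and the comparison of promoter with distal scores were therefore not run. The rule for named genes, which was to take the genes with start sites nearest to the 20 highest-scoring peaks and up to 4 per list, could not be applied, and the highest-scoring peaks are given by position. The release 6 table served to count genes per chromosome arm and, in the closing section, to see which genes neighbour each other.

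Peaks per arm were compared with the 17796 annotated genes of the X, 2L, 2R, 3L, 3R, 4 and Y, by an exact two-sided binomial test per arm with Benjamini-Hochberg adjustment over the 7 arms. Heterochromatin scaffolds were counted with their arm. All ratios share 1 total, so a surplus on 1 arm lowers the ratios of the others. Peaks were also counted in the complete 1 Mb windows between the start of each arm and its last peak, by peak centre, and the X was compared with the windows of 2L, 2R, 3L and 3R by a two-sided permutation test with 100000 resamples. Spacing was measured from the end of a peak to the start of the next, and the share under 2 kb was compared with 10000 random placements of the same peaks on the same arm. Shares carry 95% Clopper-Pearson intervals, which cover counting error only. Peaks close to each other are not independent. The p-values of the binomial test, Fisher's exact test and the permutation tests of medians are therefore too small where peaks cluster. The window test treats neighbouring windows as independent and the X is a single chromosome, so its p-value is too small as well. The window test is given beside the X alone. The other arms have the binomial test only. The repeat length of the array on 2L was the lag between 3 and 8 kb with the highest autocorrelation of peak coverage at 10 bp resolution, compared with 1000 shuffles of the same widths and gaps.

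The statistics were tested on simulated data. With 5954 simulated scores, a background set at 63.4 was recovered at 63.4, and 3.88% of peaks simulated above the background fell on the ladder by chance. The arm test called the X in 0.5% of 200 draws without an effect and in 100% of draws with the X rate raised 2-fold. The spacing test called 5% of 20 unstructured draws and 100% of 20 draws with 30 close pairs. A repeat of 4700 bp was recovered at 4700 bp. Alternatives fixed before the data were examined were a restriction to peaks scoring at or above the median, merging of peaks closer than 500 bp, a spacing limit of 5 kb and the main euchromatic arms alone. The ladder, the array, the split of the X windows by position and the other alternatives were chosen after the data were seen. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.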

Results

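Binding of GFP-tagged Lola-PJ was profiled by chromatin immunoprecipitation and sequencing in 0 to 12 h embryos. Lola is known for its many protein isoforms and for its part in axon guidance. The comparison was between 2 GFP immunoprecipitates and 2 input DNA libraries, and it asked where in the genome the immunoprecipitate was enriched over input. The series holds no immunoprecipitate from embryos without the tag. Enrichment over input therefore cannot be told apart from pull-down that does not depend on Lola-PJ. Its outcome was 1 list of 5954 peaks, called by the authors over the whole series. No spread between replicates could be measured from it, and the intervals below cover counting error only.

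Most peaks lay outside the assembled chromosomes. The unplaced sequence collections U and Uextra, which gather contigs that release 5 did not assign to a chromosome, held 4762 peaks, 79.98% of the list (95% interval 78.9 to 81.0%). Of these, 4305 were on Uextra and 457 on U. The main arms X, 2L, 2R, 3L, 3R and 4 held 1157 peaks, 19.4% of the list (18.4 to 20.5%). The heterochromatin scaffolds held 33 peaks and the mitochondrial genome 2. Peaks covered 674 kb of the main arms and 1941 kb of U and Uextra. The median width on the main arms was 411 bp, with quartiles of 266 and 756 bp. The median width on U and Uextra was 380.5 bp, with quartiles of 282 and 480.0 bp.

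The peak scores fell on a regular ladder. Among 53 scores that were each held by at least 15 peaks, 52 equalled −log10 of a Poisson probability at a single background mean of 49.15 overlapping fragments, within 0.01, for pileups from 91 to 143 fragments. Over the whole list 4123 peaks, 69.2% (68.1 to 70.4%), were on this ladder. A ladder moved midway between its steps matched 1.09%, and no ladder with a mean more than 1 away matched over 17.0%. A peak on the ladder cannot lie on the moved one, so 1.09% understates the matches by chance. In the simulation 3.88% of peaks above the background matched by chance. The ladder gives each of these peaks a fold over the fixed background. The median fold was 2.30, with quartiles of 2.14 and 2.52.

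**Figure D1:**
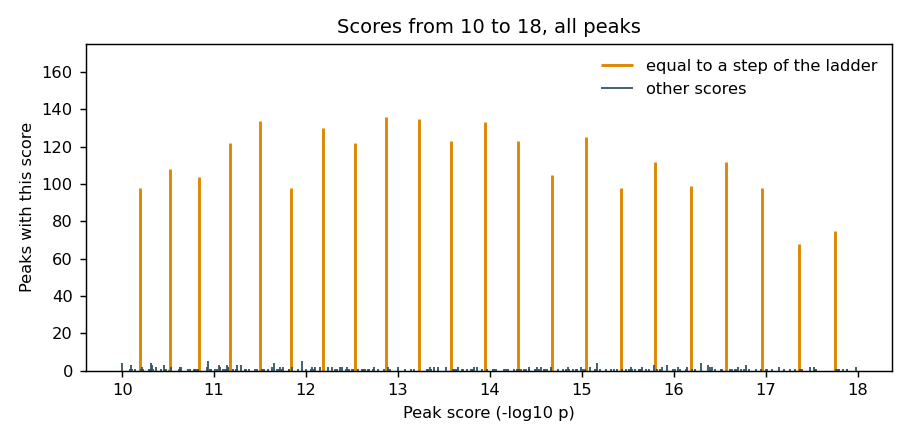
Number of peaks (vertical axis) holding each score from 10 to 18 (−log10 p, horizontal axis), with scores within 0.01 of a step of the Poisson ladder in orange and all other scores in blue. The orange scores stand at the steps for a background mean of 49.15 fragments.

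The X chromosome carried more peaks than its number of genes would give. With its scaffold it held 357 of the 1190 peaks on chromosomes, against 181 expected, a ratio of 1.98 (95% interval 1.81 to 2.15, adjusted p = 2.73e-37, exact binomial test). The direction turned among peaks off the fixed background, where the X stood at 0.63 (0.48 to 0.81, adjusted p = 0.000407, exact binomial test). That split is read as a sorting of peaks by local input, so it is not a check on the excess. The rate over all peaks is given next. That is 13.2 peaks per 100 genes on the X and 5.55 on the autosomes. With a peak array on 2L counted, arm 3R held the fewest among the large arms, 189 peaks or 0.67 of expectation (0.58 to 0.76, adjusted p = 1.16e-10, exact binomial test). With that array left out, 2L stood lowest at 0.63, and 3R stood at 0.72. Arm 2R stood at 0.84 (0.74 to 0.95, adjusted p = 0.0118 in the exact test). All arms share 1 total, so the surplus on the X lowers the other ratios. Per 100 genes 2L held 6.47 peaks, 2R 5.62, 3L 5.92 and 3R 4.47, against 5.55 on the autosomes together. The call on 2R is therefore not a lack of peaks relative to the other autosomes. Arms 2L and 3L did not pass the exact test, with ratios of 0.97 (adjusted p = 0.61) and 0.88 (adjusted p = 0.0738). Chromosome 4 held 4 peaks, and the Y, represented by its heterochromatin scaffold, held 2 (0.24 of expectation, adjusted p = 0.0377, exact test). The calls on 2R and the Y depended on the setting: in exact tests 2R did not pass after merging of peaks closer than 500 bp (0.88, adjusted p = 0.107) or without a peak array on 2L (0.91, adjusted p = 0.189), and the Y stood at 0.98 against protein-coding genes (adjusted p = 1.0). Among peaks off the fixed background 2R turned to 1.12 (adjusted p = 0.273, exact test), and without the array it passed above expectation there, at 1.32 (adjusted p = 0.00216). Arm 2L passed above expectation among peaks scoring at or above the median (1.29, adjusted p = 0.00582, exact test) and among the 290 strongest arm peaks (1.49). Without the array these ratios became 0.74 (adjusted p = 0.0202, exact test) and 0.81 (adjusted p = 0.204, exact test). It passed below expectation after the 500 bp merging (0.81, adjusted p = 0.00818, exact test) and, over all peaks, without the array (0.63). Arm 3L passed below expectation among peaks scoring at or above the median (0.76, adjusted p = 0.014, exact test), and 3R did not pass among peaks tested above the fixed background (0.88, adjusted p = 0.259).

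**Figure D2:**
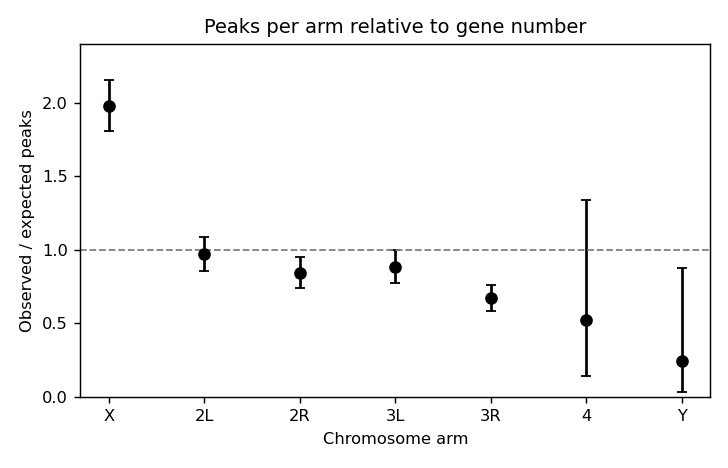
Ratio of observed to expected peaks (vertical axis, linear from 0) for each chromosome with its heterochromatin scaffold, the expectation being its share of annotated genes. Points are ratios and bars are 95% Clopper-Pearson intervals, and the X stands at 1.98 with the dashed line at 1.

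The 22 complete windows of 1 Mb on the X held 15.9 ± 8.66 peaks (mean ± SD), and the 94 windows of the large autosomal arms held 7.32 ± 4.03 when the array on 2L was left out. The difference of 8.59 peaks per window had p = 2.0e-05 in a permutation test, the smallest value its resamples can give. The first 11 windows of the X held 237 peaks (21.5 ± 8.09 per window) and the last 11 held 113 (10.3 ± 4.71), a difference that was not tested. With the array included the autosomal windows held 8.28 ± 9.70 peaks and p was 0.0026 in the same permutation test. Neighbouring windows are not independent and the X is a single chromosome, so both p-values of this test are too small. Of the 10 windows with the most peaks outside the array, 8 were on the X. The densest were the windows from 3000001 to 4000000 with 37 peaks and from 8000001 to 9000000 with 33 peaks.

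**Figure D3:**
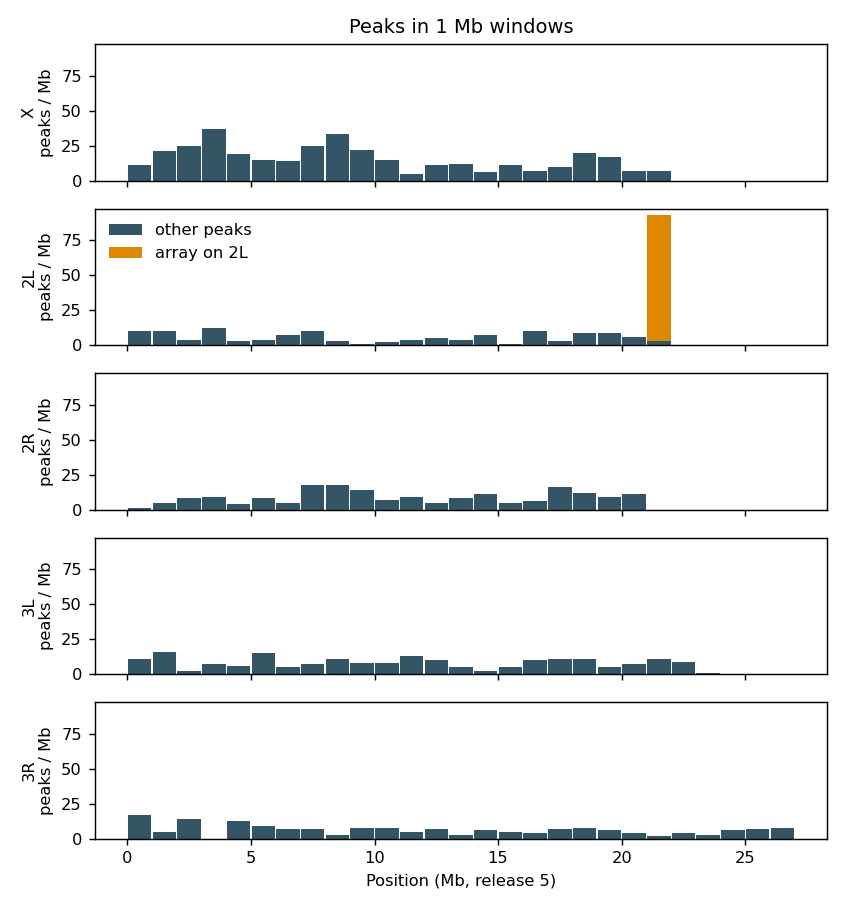
Number of peaks in each 1 Mb window (vertical axis) along the 5 large chromosome arms (horizontal axis, Mb in release 5), with peaks of the 2L array in orange and other peaks in blue. The windows on the X reach 37 peaks, and the array fills 1 window of 2L.

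Peaks on the X and on the autosomes were of similar size but were scored differently. Median width was 416.5 bp on the X and 385 bp on autosomes without the array, a difference of 31.5 bp that did not pass a permutation test (adjusted p = 0.245). Median score was 13.23 and 13.59 (adjusted p = 0.549, permutation test). Peaks at the fixed background made up 85.4% of the X peaks (81.3 to 88.9%) and 43.5% of the autosomal peaks (39.8 to 47.2%, Fisher's exact test, adjusted p = 1.24e-41 over 5 comparisons). The same held among scores from 10 to 20, with 93.7% on the X and 46.0% on autosomes (adjusted p = 3.88e-32, Fisher's exact test). Neighbouring peaks are not independent and the X is 1 chromosome, so both p-values from Fisher's exact test are too small. Peaks at the fixed background were 3.17 times as frequent on the X as its genes would give (2.90 to 3.43), and the other peaks stood at 0.63 (0.48 to 0.81, adjusted p = 0.000407, exact binomial test), or 0.74 without the array on 2L (0.56 to 0.95, adjusted p = 0.0406).

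Peaks lay closer together than chance placement. On the main arms 28.4% of neighbouring peaks (25.8 to 31.1%) were less than 2 kb apart, and random placement gave 2.73% (permutation p = 0.0002, the smallest value that 10000 placements can give). After merging of peaks less than 500 bp apart the share was 11.02%. Peaks that close were not shown to be separate sites, so 28.4% is not a share of separate sites. Among peaks scoring at or above the median the share was 18.2% (permutation p = 0.0002 for this and for the merged peaks, again the smallest). Without the array the share was 22.5% against 2.60% (permutation p = 0.0002, again the smallest). The X reached 28.5% against 4.01% for its own random placement. The autosomes without the array reached 19.5% against 1.91%. The observed shares of the X and the autosomes differed (p = 0.00138, Fisher's exact test). Random placement alone also gave the X the higher share, so this difference does not show stronger clustering on the X.

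A single array on 2L held more peaks than any other stretch of the main arms. Between positions 21416715 and 21543666, a stretch of 127 kb, lay 90 peaks, 40.0% of all peaks on that arm (33.5 to 46.7%). Peaks covered 59.9% of it. The next longest run of peaks with neighbours within 15 kb held 7. The peaks recurred with a lag of 5040 bp, at an autocorrelation of 0.44, while the highest of 1000 shuffles of the same peaks and gaps reached 0.24. The widest spacing between neighbours, 9747 bp from end to start, left positions 21440918 to 21450663 without peaks. Only 5.56% of the array peaks (1.83 to 12.5%) were at the fixed background, against 43.5% of other autosomal peaks (adjusted p = 1.64e-14, Fisher's exact test). The array is 1 locus chosen from these data and its peaks are not independent, so that p-value is too small. With the array left out, 2L held 137 peaks and its ratio fell from 0.97 to 0.63 (adjusted p = 7.38e-10, exact binomial test).

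**Figure D4:**
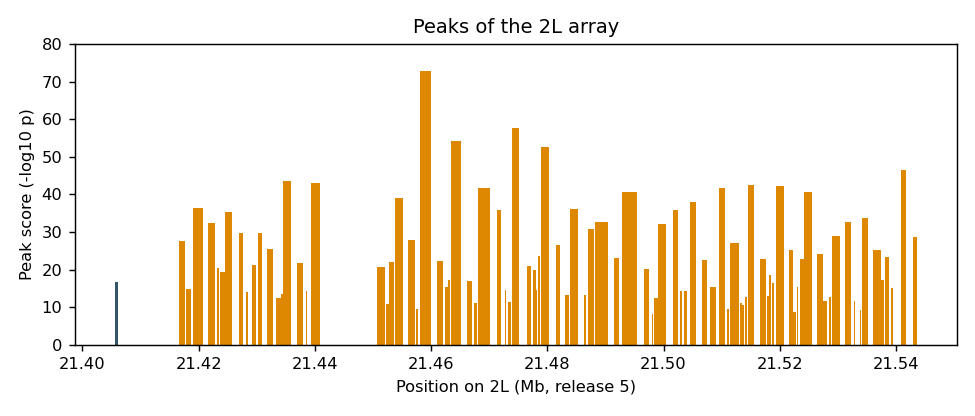
Peaks around the array on 2L, each drawn from its start to its end (horizontal axis, Mb in release 5) at the height of its score (vertical axis, −log10 p), with the 90 array peaks in orange and a neighbouring peak in blue. High peaks recur about every 5040 bp, and the stretch from 21440918 to 21450663 is empty.

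The strongest peaks were mostly in unplaced sequence. Of the 20 highest scores in the list, 18 were on U or Uextra, up to 560.36 at Uextra positions 23790145 to 23790951. Scores on U and Uextra had a median of 16.96, against 13.58 on the main arms without the array (difference 3.38, adjusted p = 8.0e-05, permutation test). On the main arms the highest score was 216.23, at X positions 10817767 to 10819764, where the pileup was 8.18-fold over the fixed background. It was followed by 198.16 at 3L positions 16045234 to 16046604, at 7.77-fold. The next was 120.94 at X positions 22422280 to 22422891, the last peak of that arm, which was not at the fixed background. Of the 20 highest-scoring arm peaks, 8 were on the X. Other peaks at the fixed background among these 20 included X positions 8315147 to 8315807 (5.11-fold), X positions 7164513 to 7166379 (5.05-fold) and 3R positions 14446740 to 14447706 (4.94-fold).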

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

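All tests in this part were chosen after the data had been seen.

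The 4762 peaks on U and Uextra lie in sequence that no comparison between chromosome arms uses, and they drew attention as a signal outside those comparisons. Local input above the genome-wide background is not the whole cause, since 73.3% of these peaks (72.0 to 74.5%) were at the fixed background. Of the 574 unplaced peaks among the 596 highest scores in the list, 9.23% (6.99 to 11.9%) were at the fixed background, so local input was raised at most of them, but their scores were already taken over that input and do not decide whether it caused the calls. The unplaced share was 96.3% among those 596 peaks and 79.98% in the whole list, so it does not come from weak calls near the threshold alone. Of the 4762 unplaced peaks, 2939 scored below 20, and the shares do not decide whether those are weak calls. Reads shared between repeat copies stay open because no sequence was examined, and no biological explanation was tested.

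The X chromosome excess, a ratio of 1.98, was not made by counting neighbouring peaks several times, since it was 1.90 (upper bound 2.12, adjusted p = 9.04e-23, exact binomial test) after merging peaks closer than 5 kb. It was not made by weak calls, since it was 1.78 (1.45 to 2.14) among the 290 arm peaks scoring 21.2 or more. An input over the X below the genome-wide background, if the ChIP libraries did not share it, cannot be told apart from enrichment on the X. The ratio among peaks off the fixed background was 0.63, and 0.74 without the array on 2L, but a lower input would move X peaks onto the fixed background whether or not it produced the excess. A difference in binding between the X and the autosomes stays open and was not tested.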

How the results depend on the processing

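The alternatives that merge within 5 kb, change the expectation, leave out the array, or use the fixed background or the 290 strongest arm peaks were chosen after the data were seen. No paired analysis was possible because the ChIP and input replicates enter 1 joint peak list with no value per library, and for the same reason no replicate could be left out. The X excess kept its call in 11 of 13 alternatives, from 1.63 with arm extents as the expectation to 3.17 at the fixed background. It reversed among peaks off that background, to 0.63, or 0.74 without the array. The split at the fixed background is read as a sorting by local input, so those ratios are not a check on the excess. Among peaks off the fixed background 2R reversed to 1.12 (adjusted p = 0.273, exact test), and without the array to 1.32, where it passed (adjusted p = 0.00216, exact test). There 3R reversed to 1.04 without passing. All arms share 1 total, so the fall of the X ratio raises the others, and the turn of 3R alone does not show a change on 3R itself. Whether 3R changed against the other autosomes was not tested. Peaks per 100 genes do not share a total. Off the fixed background and without the array they were 3.51 on 2R, 3.10 on 3L, 2.75 on 3R, 1.96 on the X and 1.83 on 2L. The high ratio of 2R there is therefore not only an effect of the shared total, but 2R was not tested against the other autosomes. The cause of the reversal on the X was not tested. Arm 2L rose above expectation for peaks scoring at or above the median (1.29), for the 290 strongest arm peaks (1.49) and off the fixed background (1.36). Without the array these became 0.74, 0.81 and 0.69, so the array peaks carried the rise. Arm 2L also fell below expectation when peaks closer than 500 bp (0.81) or 5 kb (0.72) were merged, without the array (0.63) and at the fixed background (0.63). At the fixed background the X, at 3.17, lowered the ratios of the other arms through the shared total. Of 13 alternatives, 2R lost its call without a change of direction in 6 and 3R in 2, and 3L gained one below expectation in 5, while the Y lost its call in 8 of 9. Scores at or above the median left 3067 peaks, with 84.8% on U and Uextra. Close neighbours stayed above random placement in all 4 alternatives, from 11.02% after merging to 31.1% with a limit of 5 kb. The alternatives for promoters, gene lists, annotation, promoter scores and motifs were not run, since they need a release 5 genome. With no read numbers, a region without a peak was not shown to be unbound.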

Other observations

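All tests in this part were chosen after the values had been seen. A hypothesis is that the array on 2L is the replication-dependent histone gene cluster, whose tandem units each hold genes of the linker and core histones. In the gene table of assembly release 6, the arm with the longest run of neighbouring protein-coding genes from families of 10 or more copies was 2L, with 111 genes against 12 on the X. They were 23 copies of His1, 23 of His2B, 23 of His3, 22 of His4 and 20 of His2A, and the array length divided by the repeat lag was 25.2, or 23.3 without its peak-free gap. The match is by copy number and arm, since coordinates of the releases were not compared, and random positions within the array are argued against, since 0 of 1000 shuffles reached its autocorrelation (permutation p = 0.001, the smallest they can give). More DNA copies than the assembly holds may raise the local input, since 5.56% of the array peaks were at the fixed background, but the scores were taken over that input and leave open whether copies account for the peaks.

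The 2 mitochondrial peaks, at positions 17526 to 17858 and 17918 to 19468, scored 23.14 and 68.26. Neither was at the fixed background. Among the heterochromatin scaffolds the highest scores were 130.88 on 2LHet (367981 to 368898), 108.06 on XHet (38 to 742) and 100.89 on YHet (137051 to 137531). With U divided into 10 equal parts, parts 8 and 9 held 159 and 164 of its 457 peaks. On Uextra the last of 10 such parts held 861 of 4305 peaks, 20.0%, and the first held 2.35%.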
